A study of Mus musculus with 36 samples.

How the data were processed

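MicroRNAs (miRNAs) were counted by small RNA sequencing in 36 libraries of mouse CD4 T cells. The labels name a TruSeq small RNA library made from total RNA, and state single-end reads where the series text states paired-end reads. The deposited values are whole-number counts, which the authors gave for each mature miRNA locus, per the file headers. The genome build is GRCm38 per the submitters' processing notes. The aligner, the counting tool, the miRNA database release, adapter removal and any use of molecular identifiers are not given in the sources used here.

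Each library held 2119 entries, of which 2110 named a mature miRNA and 9 were named STD. The STD entries name no miRNA, and the labels do not say what they are. They took 32.0% to 86.7% of the counts of a library and were kept out of library sizes and tests. A mature miRNA encoded at several loci had an entry per locus, and for 53 of the 61 such miRNAs with counts the locus totals lay within 10% of each other, so that reads matching several loci appeared to be counted at each. The entry with the highest total was therefore used for each of the 1966 mature names. Members of near-identical families, such as the let-7 and miR-669 miRNAs, can share reads under such counting, and their separate values are uncertain. Whether counting used strand is not given in the sources used here.

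Samples were grouped by genotype and by the time in culture that the sample labels give. Replicates of a group were compared by a chi-square test of their counts. The lowest statistic per degree of freedom among the 48 pairs was 1.69 and the highest p was 0.000855, so that no pair had the agreement of 1 library deposited more than once. miRNA counts per library ran from 64264 to 273724 in the AGO1/3/4 experiment and from 596 to 58357 in the AGO2 experiment. A floor of 3 counts, the upper limit that a count of 0 allows, equals 11.0 to 46.7 CPM (counts per 1e6 miRNA counts) per library in the AGO1/3/4 experiment and 51.4 to 5034 CPM in the AGO2 experiment. Floors and counting intervals cover counting error only.

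Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the filterByExpr filter at its minimum of 10 counts and Benjamini-Hochberg adjustment. A miRNA was called when the adjusted p was under 0.05, with no minimum fold. Each experiment was fitted as a whole with a mean per group, and the difference between the knockout effects was fitted on all 36 libraries. Levels are CPM after TMM normalisation, given as mean ± SD, and changes are log2 fold changes with the standard error (SE) implied by the test. All changes are relative to the other miRNAs of a library.

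Lists of miRNAs were tested with camera in limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation. The lists were a core set of T cell miRNAs, the let-7, miR-15/16, miR-181, miR-29 and miR-30 families, the miR-17-92 clusters with their paralogs, the miR-23-27-24 and miR-183-96-182 clusters, miRNAs induced by or lost on T cell activation, regulators of Th2 differentiation, miRNAs that depend on AGO2 slicing, Drosha-independent miRNAs, the imprinted Dlk1-Dio3 cluster, the Sfmbt2 intron cluster, and markers of myeloid cells, of red cells and platelets, of endothelial and stromal cells, and of epithelial, liver and muscle cells. Lists with fewer than 3 tested members were described by member. The share of the less abundant arm of each hairpin was compared as the library median of the log2 ratio of minor to major arm, with a pseudocount of 0.5 and a two-sided exact permutation test.

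miRNAs named in the text were chosen by a rule. For each comparison of genotypes or times it took the 8 called miRNAs with the largest increase and the 8 with the largest decrease among those with a mean of at least 10 CPM in a group, the core set, and up to 4 members of each list that passed. For differences of effects it took the 4 with the smallest p in each direction. Members called at all 3 stages, miR-30d-5p in naive cells, miR-146b-5p, miR-877-5p, miR-298-5p, miR-221-3p, miR-181b-5p and the other miR-132/212 members at day 14, shared calls and miRNAs named under the observations were chosen after their values were seen. Where a named miRNA had 0 counts in a group, the fold is a lower bound against the library of that group with the highest floor. Where it had 1 to 3 counts, the ratio of counts is given with an exact 95% binomial interval.

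The groups, the tests, the lists, the rule for named miRNAs and the alternatives were fixed before the data were examined, except for 5 alternatives chosen after seeing the data. Those added later are all locus entries as deposited, scaling to the STD entries, loess offsets against abundance, leaving out the naive Cre libraries B and C together, and thinning of libraries to 1 depth for the arm test. The alternatives fixed beforehand were DESeq2 size factors in edgeR, library size as the only scaling, no filter on low counts, the Wald test of DESeq2 1.42.0, a fit of the compared groups alone, a block for the replicate number, leaving out each library in turn, an estimated correlation for the lists, a pseudocount of 5 or no filter for the arms and a minimum mean of 100 CPM for the correlation of effects.

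The tests were checked on simulated counts with known fold changes. For the naive AGO1/3/4 comparison, 386 simulated miRNAs passed the filter. Calls were made for 9 of 23 changed by 1.5-fold, 14 of 20 by 2-fold and 25 of 28 by 4-fold. The 6 false calls among 315 unchanged miRNAs were 11.1% of calls. For naive AGO2, on 110 miRNAs, calls were 3 of 7 changed by 4-fold, 1 of 14 by 2-fold and 2 of 14 by 1.5-fold. The 1 false call among 75 unchanged was 14.3%. For AGO2 Th2, on 106 miRNAs, calls were 11 of 11 changed by 4-fold, 4 of 11 by 2-fold and 0 of 12 by 1.5-fold. Of 72 unchanged, 0 were called. The arm test gave 0.97 on 67 simulated hairpins with a doubled minor arm (exact permutation p = 0.0286) and -0.02 without (exact p = 0.829). This does not test the 9 hairpins of the AGO2 experiment.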

Results

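Small RNA sequencing counted miRNAs in CD4 T cells of C57BL/6J mice, sorted from spleen as CD4+ TCRb+ cells. Argonaute (AGO) proteins bind miRNAs and carry them to their target mRNAs. The first experiment compared wild-type (WT) cells with cells lacking AGO1, AGO3 and AGO4 (AGO134 knockout) in naive cells (4 and 4 libraries), after 7 days of culture as T helper 2 (Th2) cells (4 and 4) and after 14 days (3 and 3). The second compared CD4-Cre control cells (Cre) with CD4-Cre cells whose Ago2 alleles are floxed (AGO2 knockout) in naive cells (3 and 4) and in Th2 cells, which the sample labels place at day 5 and the series text at day 7. The Ago genes themselves are not measured by miRNA counts, so the genotype labels were not checked. The labels do not say that replicates are separate animals, and p-values measure the spread between these samples.

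Depth differed between groups. miRNA counts per library averaged 223239 in naive WT and 143644 in naive AGO134 knockout, 255368 and 172294 at day 7, and 260868 and 210699 at day 14. They averaged 3798 in naive Cre, 11062 in naive AGO2 knockout, 51315 in Th2 Cre and 28704 in Th2 AGO2 knockout. The naive Cre libraries A, B and C held 8643, 596 and 2156 miRNA counts. A library detected 386 to 737 miRNAs in the first experiment and 73 to 420 in the second. miR-5099 took 0.836% to 1.87% of miRNA counts per library in the first experiment and 9.85% to 65.8% in the second.

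The first question was how the loss of AGO1, AGO3 and AGO4 alters the miRNAs of naive cells. miR-150-5p, which restrains Myb in mature lymphocytes, stood at 60752 ± 15768 against 37795 ± 3976 CPM (SD, n = 4 and 4; log2 fold change 0.68 with SE 0.15, edgeR adjusted p = 0.00236). let-7g-5p (MIMAT0000121; GRCm38 chromosome 9, 106178840 to 106178927, in an intron of Wdr82) stood at 36394 ± 11125 against 23441 ± 2419 CPM (log2 fold change 0.63 with SE 0.15, edgeR adjusted p = 0.00329). miR-877-5p (MIMAT0004861; chromosome 17, 35960730 to 35960814, in an intron of Abcf1), a mirtron made by splicing without Drosha, fell to 45.9 ± 19.1 against 160 ± 32.99 CPM (log2 fold change -1.96 with SE 0.28, edgeR adjusted p = 2.2e-05). For these 3 miRNAs, all 4 knockout libraries lay beyond every WT library.

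In naive cells, edgeR called 7 of 10 tested higher and 0 lower, or 7 adjusted over the list alone (camera adjusted p = 5.3e-05, or 0.187 with an estimated correlation) in the let-7 family, with a median log2 fold change of 0.53 that became -0.31 when libraries were scaled to the STD entries. Its members let-7a-5p, let-7c-5p and let-7f-5p had log2 fold changes of 0.78, 0.69 and 0.67. Knockout library 4 had the highest level of each (108400, 66425 and 108017 CPM), and without it the values were 0.48, 0.44 and 0.40, each still called. Depth moved with genotype beside these lists, at 143644 ± 56295 miRNA counts per knockout library and 223239 ± 20647 per WT library. Among miRNAs known to be lost on T cell activation, edgeR called 6 of 17 tested higher and 0 lower, or 6 adjusted over the list alone (camera adjusted p = 0.0170, or 0.176 with an estimated correlation); their median of 0.18 became -0.13 with library size as the only scaling and -0.57 with scaling to the STD entries. Of the core set of T cell miRNAs, 5 of 12 tested members rose and 0 fell, with 5 adjusted over the list alone. These were miR-150-5p, let-7g-5p, miR-181a-5p, which sets T cell receptor sensitivity (0.62), miR-146a-5p, a brake on NF-kB signalling (0.53), and miR-155-5p, which T helper responses need (0.46). The members that did not pass were miR-21a-5p (0.19), miR-142a-3p (0.39), miR-142a-5p (0.23), miR-17-5p (0.07), miR-24-3p (0.10), miR-27a-3p (0.18) and miR-29a-3p (0.15). All 5 rises and the values of miR-21a-5p, miR-24-3p, miR-27a-3p and miR-29a-3p turned negative when scaled to the STD entries.

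miR-92a-3p, a product of the miR-17-92 cluster, rose in naive cells to 3564 ± 3359 against 1222 ± 88.2 CPM (log2 fold change 1.46 with SE 0.34, edgeR adjusted p = 0.00335). All 4 knockout libraries lay above every WT library, but knockout library 4 alone held 8594 CPM, and without it the log2 fold change was 0.66 (adjusted p = 0.0331). Other rises were those of miR-3963 (0.66), miR-466m-5p (0.87), miR-669m-5p (0.86) and miR-30d-5p (0.55). miR-466m-5p and miR-669m-5p had nearly the same values in each library and are not taken as separate measurements. Among the decreases were miR-1839-3p (-1.94), miR-3473d (-1.87), miR-6957-5p (-1.59), miR-1934-5p (-1.47) and miR-331-3p (-1.45). The call of miR-184-3p (-2.27) rested on WT library 1, with 132 of 155 WT counts; without it the counts were too low for the test, and the count ratio of WT to knockout was 1.08 (95% interval 0.544 to 2.18). miR-301b-3p had 22 counts in WT and 3 in the knockout, a ratio of 3.91 (95% interval 1.18 to 20.4).

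Of 382 miRNAs tested in naive cells, edgeR called 70, of which 31 were higher and 39 lower, and 12 changed by 2-fold or more. The direction depended on scaling, filter and the groups fitted. The split was 36 higher and 30 lower with DESeq2 size factors, 40 and 26 with DESeq2, 8 and 80 with library size alone, 0 and 204 with STD scaling, 6 and 46 with these groups fitted alone, 14 and 37 with no filter and 28 and 63 with all locus entries. Without WT library 1 or knockout library 4 the calls were 37 and 46. Log2 values were -2.67 for miR-3473d (on 2 counts) without knockout 1, -2.68 for miR-1839-3p without knockout 2 and -1.28 for miR-3473d without knockout 3. Values on 1 to 3 counts, here and below, are no bound. Calls of miR-184-3p and miR-301b-3p ended with DESeq2 size factors. Those of miR-184-3p, miR-301b-3p and miR-6957-5p ended with DESeq2. Those of miR-146a-5p, miR-155-5p, miR-181a-5p, miR-466m-5p and miR-669m-5p ended with library size alone. Those of miR-155-5p, miR-301b-3p, miR-466m-5p and miR-669m-5p ended with no filter. Those of let-7a-5p, let-7f-5p, let-7g-5p, miR-150-5p, miR-155-5p and miR-301b-3p ended with loess offsets. Those of let-7a-5p, let-7c-5p, let-7f-5p, let-7g-5p, miR-150-5p, miR-155-5p, miR-181a-5p, miR-466m-5p and miR-669m-5p ended with these groups fitted alone. Calls of miR-155-5p and let-7f-5p (WT 1), miR-184-3p (knockout 1, 3 or 4), miR-301b-3p (WT 1, 2 or 3, knockout 1, 3 or 4), miR-1934-5p (WT 1, 2 or 3, knockout 1, 2 or 4), miR-466m-5p and miR-669m-5p (WT 1, 2 or 3, knockout 1 or 4) and miR-3473d (knockout 2 or 3) ended without any 1 library in brackets. miR-877-5p, miR-331-3p and miR-1839-3p kept their call under every alternative that gave a value, and miR-92a-3p under all but STD scaling.

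The same question was asked after 7 days as Th2 cells. miR-27a-3p and its cluster partner miR-24-3p, which restrain Th2 responses, stood at 9933 ± 1676 against 6129 ± 747 CPM and 16525 ± 1044 against 12811 ± 789 CPM in knockout and WT (SD, n = 4 and 4; log2 fold changes 0.69 and 0.37, edgeR adjusted p = 0.000477 and 0.0346). miR-155-5p (MIMAT0000165; chromosome 16, 84714140 to 84714204, in an exon of Mir155hg) stood at 13733 ± 1723 against 9598 ± 413 CPM (log2 fold change 0.52 with SE 0.12, edgeR adjusted p = 0.00619), and miR-21a-5p, which activated T cells induce, at 37956 ± 5452 against 24046 ± 1757 CPM (log2 fold change 0.66 with SE 0.13, edgeR adjusted p = 0.000997). miR-877-5p was again lower, at 162 ± 28.6 against 329 ± 17.3 CPM (log2 fold change -0.99 with SE 0.17, edgeR adjusted p = 0.000670). All 4 knockout libraries lay beyond every WT library for each of these 5 miRNAs.

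Several lists rose at day 7, where knockout libraries held 172294 ± 31194 and WT libraries 255368 ± 27200 miRNA counts. In the miR-23-27-24 clusters edgeR called 5 of 11 tested higher and 0 lower, or 6 adjusted over the list alone (camera adjusted p = 0.000246, or 0.0323 with an estimated correlation), with miR-23a-3p at 0.54 and miR-27b-3p at 0.49. Among regulators of Th2 differentiation edgeR called 8 of 15 tested higher and 0 lower, or 8 adjusted over the list alone (camera adjusted p = 0.000111, or 0.0323 with an estimated correlation). The medians of both lists, 0.37, became -0.25 with STD scaling. Among miRNAs induced by T cell activation edgeR called 6 of 21 tested higher and 0 lower, or 6 adjusted over the list alone (camera adjusted p = 0.000111, or 0.0610 with an estimated correlation), with miR-182-5p at 0.57; the median of 0.33 became -0.31 with that scaling. In the let-7 family edgeR called 4 of 10 tested higher and 0 lower, or 6 adjusted over the list alone (camera adjusted p = 0.00327, or 0.254 with an estimated correlation); the median of 0.37 became -0.25 with that scaling and fell just below 0 with loess offsets. In the miR-17-92 clusters edgeR called 4 of 18 tested higher and 0 lower, or 5 adjusted over the list alone (camera adjusted p = 0.0105, or 0.105 with an estimated correlation), with miR-25-3p (0.48), miR-93-5p (0.45) and miR-17-3p (0.45); the median of 0.23 became -0.09 with library size alone and -0.40 with STD scaling. In the miR-30 family edgeR called 2 of 5 tested higher and 0 lower, or 3 adjusted over the list alone (camera adjusted p = 0.0377, or 0.176 with an estimated correlation), with miR-30d-5p at 0.74 and miR-30e-5p at 0.60; the median of 0.38 became -0.21 with STD scaling.

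Of the core set at day 7, 6 of 12 tested members rose and 0 fell, and 7 passed adjusted over the list alone. Besides those named, miR-146a-5p (0.45) and let-7g-5p (0.44) rose. The others were miR-150-5p (0.36), miR-142a-3p (0.30), miR-142a-5p (0.20), miR-181a-5p (-0.24), miR-17-5p (0.35) and miR-29a-3p (-0.08). Other rises were those of miR-210-3p (0.89), miR-7a-5p (0.74), miR-125a-3p (0.69), miR-132-5p (0.67) and let-7i-5p (0.56). miR-7072-5p had 12 counts in the knockout and 3 in WT, a ratio of 7.29 (95% interval 1.97 to 40.3). The decreases were led by miR-301a-5p (-1.23), miR-139-3p (-1.23), miR-1934-5p (-1.20), miR-186-3p (-1.08), miR-455-3p (-1.07), miR-326-3p (-0.999) and miR-15b-3p (-0.99).

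Of 382 miRNAs tested at day 7, edgeR called 55, with 33 higher and 22 lower, and 6 changed by 2-fold or more. The split was 4 higher and 43 lower with library size alone, 1 and 128 with STD scaling, and 15 and 22 with loess offsets. Without WT library 2, 3 or 4 the calls were 34, 36 and 36, without knockout library 4 they were 24, and with no filter on low counts they were 35, 13 higher and 22 lower. Calls of let-7g-5p, let-7i-5p and miR-25-3p ended with DESeq2 size factors. Those of let-7g-5p, miR-139-3p, miR-186-3p, miR-1934-5p, miR-210-3p, miR-301a-5p, miR-326-3p and miR-7072-5p ended with DESeq2. Those of let-7g-5p, let-7i-5p, miR-125a-3p, miR-132-5p, miR-146a-5p, miR-155-5p, miR-17-3p, miR-182-5p, miR-210-3p, miR-21a-5p, miR-23a-3p, miR-24-3p, miR-25-3p, miR-27b-3p, miR-30e-5p, miR-7a-5p and miR-93-5p ended with library size alone. Those of let-7g-5p, miR-125a-3p, miR-132-5p, miR-139-3p, miR-146a-5p, miR-155-5p, miR-17-3p, miR-186-3p, miR-23a-3p, miR-24-3p, miR-25-3p, miR-27b-3p and miR-93-5p ended with no filter. Those of let-7g-5p, let-7i-5p, miR-125a-3p, miR-139-3p, miR-146a-5p, miR-24-3p and miR-25-3p ended with all locus entries. Those of let-7g-5p, let-7i-5p, miR-139-3p, miR-146a-5p, miR-155-5p, miR-182-5p, miR-21a-5p, miR-24-3p, miR-25-3p, miR-27b-3p and miR-93-5p ended with loess offsets. Those of miR-132-5p, miR-1934-5p and miR-7a-5p ended with these groups fitted alone. Calls of miR-24-3p and let-7g-5p (WT 2, 3 or 4, knockout 1, 3 or 4), miR-146a-5p (WT 1, knockout 1), let-7i-5p (WT 2 or 3, knockout 1 or 4), miR-25-3p (WT 2, 3 or 4, knockout 1 or 4), miR-17-3p and miR-301a-5p (knockout 4), miR-30e-5p (WT 1 or 2, knockout 1, 3 or 4), miR-210-3p and miR-1934-5p (WT 1, knockout 4), miR-7a-5p (WT 1, 2 or 4, knockout 1 or 4), miR-125a-3p and miR-139-3p (WT 2, 3 or 4, knockout 2, 3 or 4), miR-132-5p (WT 1 or 2, knockout 4), miR-7072-5p (knockout 3), miR-186-3p (WT 4, knockout 4) and miR-326-3p (WT 2 or 4, knockout 3 or 4) ended without any 1 library in brackets. The calls of miR-877-5p, miR-455-3p and miR-15b-3p did not end under any alternative, and those of miR-27a-3p and miR-30d-5p ended only with STD scaling.

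At day 14, 40 miRNAs changed by 2-fold or more, against 6 at day 7. miR-212-5p (MIMAT0017053; chromosome 11, 75173388 to 75173478, in an intron of 1700016P03Rik), of the miR-132/212 cluster that CREB induces on activation, fell to 467 ± 143 against 2553 ± 139 CPM (SD, n = 3 and 3; log2 fold change -2.45 with SE 0.22, edgeR adjusted p = 3.5e-09). miR-10a-5p (MIMAT0000648; chromosome 11, 96317165 to 96317274), known from regulatory T cells, fell to 324 ± 90.6 against 1559 ± 44.0 CPM (log2 fold change -2.28 with SE 0.31, edgeR adjusted p = 2.4e-06), and miR-146b-5p (chromosome 19, 46342762 to 46342870, in an intron of Mfsd13a), a paralog of miR-146a, to 311 ± 50.3 against 966 ± 64.5 CPM (log2 fold change -1.64 with SE 0.19, edgeR adjusted p = 4.1e-07). miR-222-3p (MIMAT0000670; chromosome X, 19146893 to 19146971), which targets the cell cycle inhibitor p27, rose to 1155 ± 223 against 388 ± 126 CPM (log2 fold change 1.58 with SE 0.20, edgeR adjusted p = 1.0e-06). For these 4 miRNAs, all 3 knockout libraries lay beyond every WT library.

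**Figure D1:**
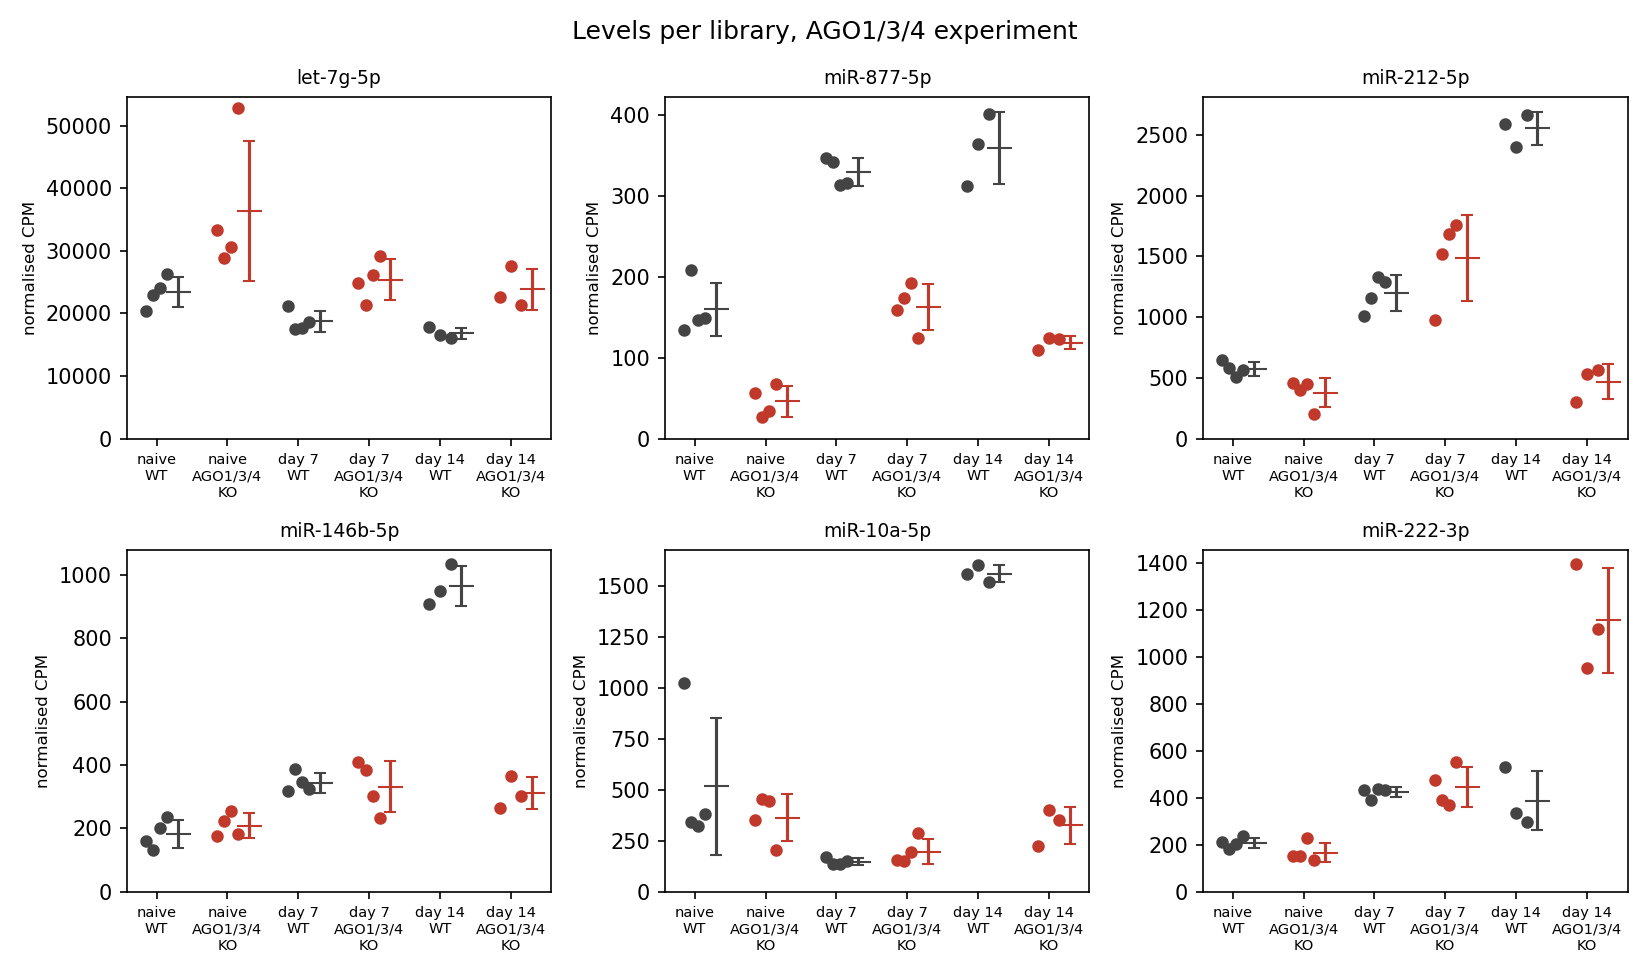
Normalised level (CPM, linear axis) of 6 miRNAs in the WT (grey) and AGO134 knockout (red) libraries of naive, day 7 and day 14 cells, with a point per library and a dash and bar for the mean ± SD. miR-212-5p stood at 467 ± 143 against 2553 ± 139 CPM in knockout and WT at day 14.

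Other decreases at day 14 were miR-10b-5p (-2.51), miR-326-3p (-2.40), miR-152-3p (-2.10), miR-98-3p (-2.04), miR-33-5p (-2.03), miR-29a-5p (-1.94), miR-212-3p (-1.81), miR-132-3p (-1.75) and miR-298-5p (-1.74), and miR-877-5p stood at 119 ± 8.21 against 359 ± 44.5 CPM (-1.60). Rises included miR-1941-5p (2.59), miR-7667-5p (1.68), miR-203-3p (1.59), miR-128-1-5p (1.57), miR-31-5p (1.15), miR-92a-3p (1.14), miR-221-3p (1.06) and miR-181b-5p (1.05), and miR-92a-1-5p rose to 3357 ± 1021 against 1560 ± 123 CPM (1.103). Of the core set, 3 of 12 tested members rose, 1 fell and 4 passed adjusted over the list alone. The rises were miR-181a-5p (0.69), miR-150-5p (0.62) and let-7g-5p (0.51) and the decrease that of miR-142a-3p (-0.74). The values of the others were miR-155-5p (-0.12), miR-146a-5p (0.18), miR-21a-5p (0.15), miR-142a-5p (0.00223), miR-17-5p (0.40), miR-24-3p (0.01), miR-27a-3p (-0.07) and miR-29a-3p (0.19). No list of 15 passed camera at day 14 (0 at adjusted p under 0.05, and 3 at an unadjusted p under 0.05, or 2 with an estimated correlation); the lowest was the list lost on activation, with 6 of 17 members higher, 6 adjusted over the list alone (adjusted p = 0.0838, 0.261 with an estimated correlation).

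Of 382 miRNAs tested at day 14, edgeR called 75, of which 34 were higher and 41 lower, and 40 changed by 2-fold or more. The split was 24 and 48 with DESeq2 size factors, 22 and 54 with library size alone, 25 and 53 with all locus entries, and 2 and 72 with STD scaling. Log2 values were -2.96 for miR-33-5p without knockout 2 and 1.04 for miR-7667-5p without knockout 4. Calls of let-7g-5p, miR-150-5p, miR-181a-5p and miR-92a-3p ended with DESeq2 size factors or all locus entries. Those of let-7g-5p, miR-150-5p, miR-181a-5p, miR-7667-5p and miR-92a-3p ended with DESeq2. That of let-7g-5p ended with no filter or a replicate block. Those of let-7g-5p, miR-150-5p and miR-92a-3p ended with loess offsets. Calls of let-7g-5p and miR-92a-3p (WT 1, 2 or 3, knockout 3 or 4), miR-150-5p (WT 1 or 3, knockout 3), miR-181a-5p (WT 2 or 3), miR-142a-3p (WT 3, knockout 3 or 4), miR-98-3p (WT 1 or 3, knockout 3 or 4), miR-7667-5p (WT 1, knockout 4), miR-128-1-5p (WT 2, knockout 4) and miR-29a-5p (knockout 4) ended without any 1 library in brackets. Those of miR-212-5p, miR-10a-5p and miR-222-3p did not end under any alternative.

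A total of 4 miRNAs were higher at all 3 stages, namely let-7g-5p, miR-140-3p, miR-30d-5p and miR-3963, and 5 were lower, namely miR-877-5p, miR-1934-5p, miR-3068-3p, miR-328-3p and miR-330-3p. Naive cells and day 7 shared 14 higher and 10 lower calls, naive cells and day 14 shared 11 and 8, and days 7 and 14 shared 7 and 8. A test of the overlap that gave every miRNA the same chance of a call is not used, since calls depend on counts. The call of let-7g-5p ended under 12 alternatives at day 7 and 11 at day 14 outside STD scaling, with which let-7g-5p and miR-3963 were lower in naive cells (-0.23 and -0.15) and 0 miRNAs were called higher there.

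No other list passed camera in an AGO134 comparison. Of 4 Drosha-independent miRNAs, 1 was lower in naive cells, miR-877-5p. Markers of endothelial and stromal cells had 0 of 4 and those of epithelial, liver and muscle cells 1 of 8 tested members called in naive cells (adjusted p = 0.209 and 0.190); 0 were tested from the myeloid list. The 2 tested markers of red cells and platelets, the 2 tested slicer-dependent miRNAs and the 1 tested Dlk1-Dio3 miRNA had 0 calls in any AGO134 comparison by edgeR. In the second experiment, no marker or slicer-dependent miRNA was tested.

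The effect of the AGO134 knockout was tested for a difference between stages. From naive cells to day 7, edgeR called 9 of 382 miRNAs, 7 with a rise of the knockout effect and 2 with a fall. miR-182-5p (0.93), miR-351-5p (0.94), miR-1839-3p (1.68) and miR-542-5p (1.05) led the rises (log2 difference of the fold changes), and miR-15b-3p (-1.22) and miR-181a-5p (-0.86) were the falls. From day 7 to day 14, 46 miRNAs differed, 21 upward and 25 downward. The knockout effect on miR-212-5p shifted by -2.76 (SE 0.28, edgeR adjusted p = 6.5e-08), on miR-212-3p by -2.32, on miR-132-5p by -1.95 and on miR-146b-5p by -1.62. That on miR-222-3p shifted by 1.52, on miR-221-3p by 1.38, on miR-15b-3p by 1.38 and on miR-181b-5p by 1.29. The first count was 3, 4 and 15 without naive WT library 1, 2 or 3, 5 without naive knockout library 2, and 3 and 4 without day 7 WT library 3 or 4; it was 3 with library size alone, 1 with STD scaling and 14 with DESeq2. Its split was 8 and 4 with DESeq2 size factors, 2 and 1 with library size alone, 1 and 0 with STD scaling, 7 and 4 with loess offsets, 9 and 1 with all locus entries, and 5 and 4 with no filter or with these groups fitted alone, and a block for replicate labels gave 5 calls. The difference was 2.33 for miR-1839-3p without naive knockout 2. Calls of miR-15b-3p, miR-1839-3p and miR-542-5p ended with library size alone. That of miR-1839-3p ended with no filter. That of miR-181a-5p ended with all locus entries. Those of miR-181a-5p and miR-1839-3p ended with a replicate block. Calls of miR-1839-3p (naive WT 1 or 2, naive knockout 1, 3 or 4, day 7 WT 3 or 4, day 7 knockout 1), miR-542-5p (naive WT 1 or 4, naive knockout 1, 2 or 4, day 7 WT 3, day 7 knockout 1) and miR-181a-5p (naive WT 1 or 2, day 7 WT 1, 3 or 4, day 7 knockout 4) ended without any 1 library in brackets. The second count was 30 without day 14 WT library 3, 15 with STD scaling, and split 24 and 14 with library size alone.

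The second experiment asked the same of AGO2, the AGO protein that can cut RNA, first in naive cells at low depth. miR-181a-5p stood at 11333 ± 6123 against 3061 ± 1534 CPM in knockout and Cre (SD, n = 4 and 3; log2 fold change 1.79 with SE 0.55, edgeR adjusted p = 0.0452), and let-7g-5p at 16296 ± 3251 against 32524 ± 7461 CPM (log2 fold change -1.01 with SE 0.31, edgeR adjusted p = 0.0452). All 4 knockout libraries lay beyond every Cre library for both. miR-3963 (3.12) also rose, and miR-3962 (-3.72), miR-148b-3p (-2.48), miR-669a-5p (-1.87), miR-669p-5p (-1.87), miR-1843a-5p (-1.75) and miR-26b-5p (-1.04) fell, where miR-669a-5p and miR-669p-5p have identical values. With these identical, the 3 tested members of the Sfmbt2 intron cluster are 2 distinct measurements and were not read as a list. Of the core set, 1 of 11 tested members rose, 1 fell, and 4 passed adjusted over the list alone. The others were miR-155-5p (0.20), miR-150-5p (1.17), miR-146a-5p (2.30), miR-21a-5p (0.35), miR-142a-3p (1.88), miR-142a-5p (0.81), miR-24-3p (0.46) and miR-27a-3p (0.06). Cre library A held all 8 Cre counts of miR-146a-5p and 115 of 117 of miR-142a-3p. Under the alternatives these values ran from 1.82 to 9.74, the latter a fit against 0 counts that is no bound, and from 1.30 to 5.81, a fit on 2 counts; both passed without library A. miR-29a-3p had 3 counts in Cre and 19 in the knockout, a ratio of 2.04 (95% interval 0.602 to 10.8).

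Of 98 miRNAs tested in naive cells of the AGO2 experiment, edgeR called 9, with 2 higher and 7 lower, all by 2-fold or more. The count was 18 without Cre library A, 5 without B, 4 without C, and 5 without knockout library D or G; 14 with library size alone, 31 with all locus entries and 5 with STD scaling. Without Cre libraries B and C, the shallowest, edgeR called 0 of 151 (21 at an unadjusted p under 0.05, smallest adjusted p = 0.0773) and DESeq2 called 3; there library A alone is assumed to vary like the other groups. The split was 4 and 5 with DESeq2 size factors, 1 and 13 with library size alone, 7 and 6 with DESeq2 or no filter, 15 and 16 with all locus entries and 3 and 3 with these groups fitted alone. Log2 values were 2.81 for miR-181a-5p without Cre A and -2.65 for miR-3962 and -0.76 for miR-1843a-5p without Cre C. Calls of miR-1843a-5p and miR-26b-5p ended with DESeq2 size factors. That of miR-26b-5p ended with DESeq2. That of miR-181a-5p ended with library size alone or loess offsets. Those of let-7g-5p, miR-1843a-5p and miR-26b-5p ended with no filter or all locus entries. Those of let-7g-5p and miR-26b-5p ended with these groups fitted alone. Calls of let-7g-5p (Cre A, B or C, knockout D or G), miR-181a-5p (Cre B or C, knockout D or G), miR-1843a-5p (Cre B or C, knockout D, E, F or G), miR-26b-5p (Cre B or C, knockout D, F or G) and miR-3962 (Cre C) ended without any 1 library in brackets.

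In Th2 cells of the AGO2 experiment, both arms of miR-150 rose, miR-150-3p (MIMAT0004535; chromosome 7, 45121757 to 45121821) to 9538 ± 1395 against 319 ± 30.0 CPM (log2 fold change 4.88 with SE 0.45, edgeR adjusted p = 3.7e-08) and miR-150-5p (MIMAT0000160) to 7089 ± 2010 against 651 ± 57.1 CPM (log2 fold change 3.43 with SE 0.47, edgeR adjusted p = 7.0e-06; SD, n = 4 and 3). miR-25-5p (MIMAT0017049; chromosome 5, 138165321 to 138165404, within Mcm7) rose to 1397 ± 396 against 88.5 ± 16.5 CPM and miR-92a-1-5p (chromosome 14, 115044427 to 115044506, in an exon of Mir17hg) to 1212 ± 236 against 123 ± 61.2 CPM; both are usually minor arms, of hairpins of the miR-17-92 cluster and its paralogs (log2 fold changes 4.04 and 3.17, edgeR adjusted p = 1.8e-07 and 3.5e-06). miR-298-5p (MIMAT0000376; chromosome 2, 174267504 to 174267585) fell to 48.5 ± 42.8 against 1314 ± 144 CPM (log2 fold change -4.23 with SE 0.44, edgeR adjusted p = 1.6e-07), and miR-212-5p to 542 ± 306 against 2751 ± 278 CPM (log2 fold change -2.12 with SE 0.31, edgeR adjusted p = 1.0e-05). For these 6 miRNAs, all 4 knockout libraries lay beyond every Cre library.

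**Figure D2:**
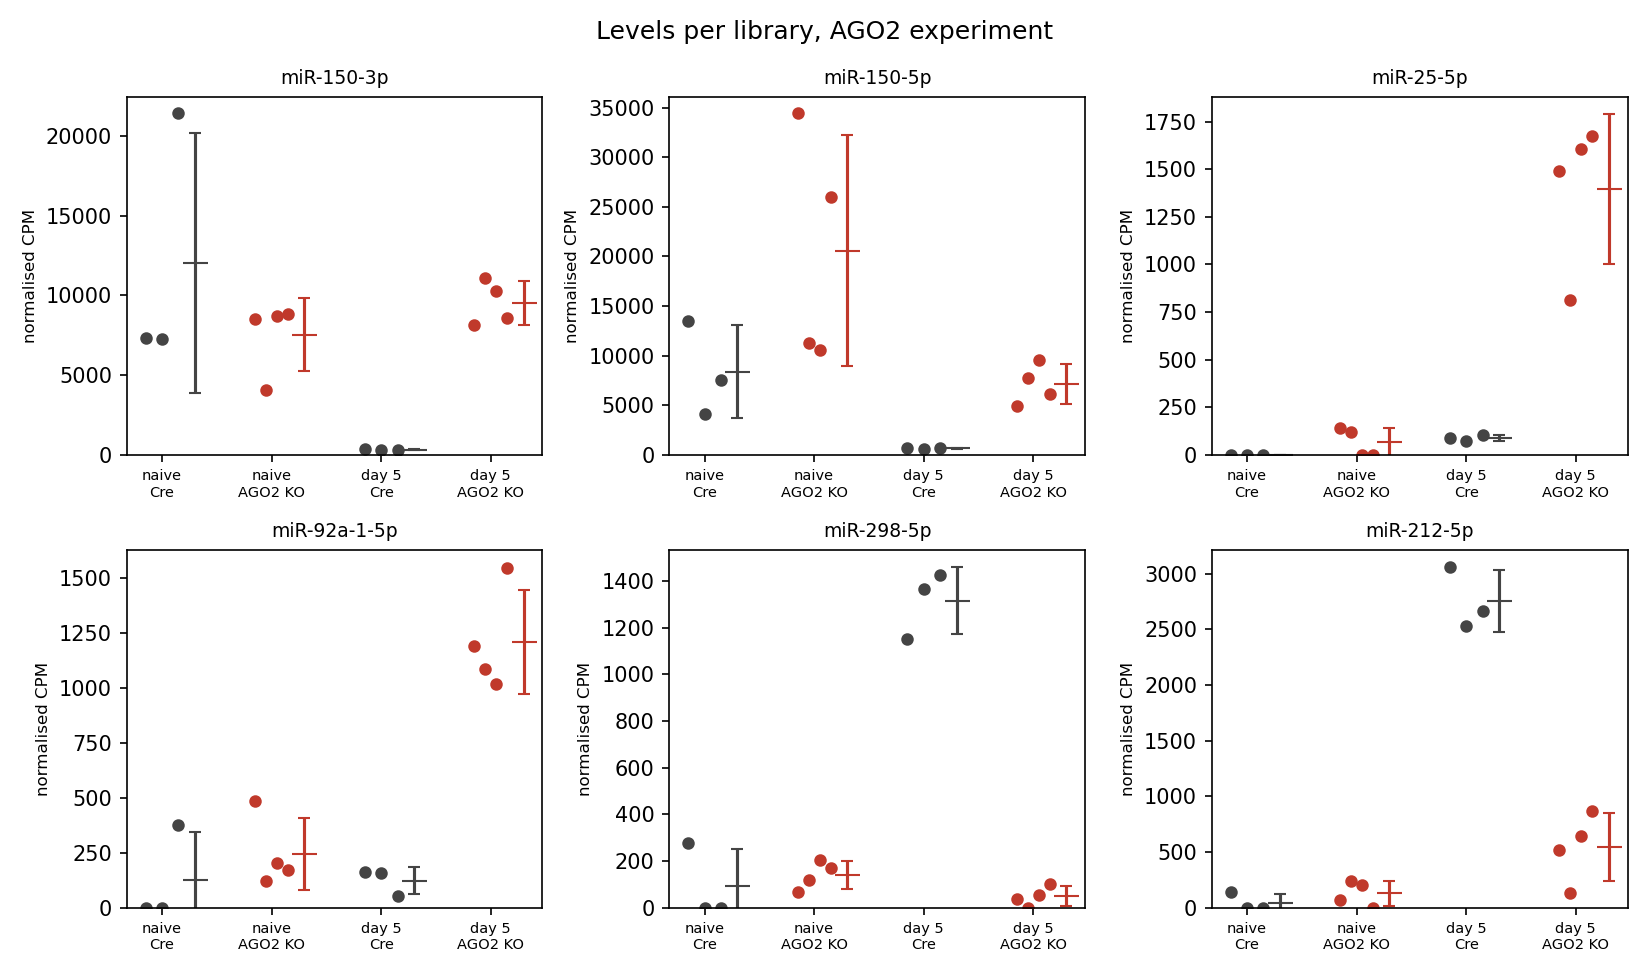
Normalised level (CPM, linear axis) of 6 miRNAs in the Cre (grey) and AGO2 knockout (red) libraries of naive and Th2 cells, with a point per library and a dash and bar for the mean ± SD. miR-150-3p stood at 9538 ± 1395 against 319 ± 30.0 CPM in knockout and Cre Th2 cells.

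Other rises were those of miR-30b-3p (2.17), miR-3963 (2.07), miR-23a-5p (1.87), miR-5099 (1.69) and miR-181a-5p (1.42), where 3 of 4 knockout libraries lay above every Cre library for miR-5099. Knockout library E alone held 795145 CPM of it. Other decreases were those of miR-700-3p (-2.26), miR-186-5p (-2.06), miR-744-5p (-2.03), miR-7a-5p (-1.96), miR-103-3p (-1.93) and miR-6538 (-1.85). The values of core members that did not pass were miR-155-5p (-0.22), miR-146a-5p (0.49), miR-21a-5p (-0.04), miR-142a-3p (0.73), miR-142a-5p (0.71), miR-24-3p (-0.73), miR-27a-3p (0.21), miR-29a-3p (0.78) and let-7g-5p (-0.00421); 2 of 11 members rose, 0 fell, and 2 passed adjusted over the list alone. No list of 8 passed camera, with 0 at an adjusted p under 0.05 and 0 at an unadjusted p under 0.05, or with an estimated correlation. Of miRNAs lost on activation, 4 of 10 were higher and 1 lower, with 6 adjusted over the list alone (adjusted p = 0.763, 0.9502 with an estimated correlation).

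Of 98 miRNAs tested in Th2 cells of the AGO2 experiment, edgeR called 44, with 19 higher and 25 lower, and 40 changed by 2-fold or more. The split was 12 and 29 with library size alone, 4 and 65 with STD scaling and 16 and 33 with DESeq2. The count was 76 with no filter on low counts (21 and 55), 71 with all locus entries, 69 with STD scaling and 79 with the Th2 groups fitted alone. The miR-181a-5p call ended without Cre library A, B or C or knockout library F, and that of miR-5099 without Cre library A, B or C or knockout library E; the values of both turned negative when scaled to the STD entries. Log2 values were 2.52 for miR-92a-1-5p without Cre C and 0.65 for miR-5099 without knockout E. The call of miR-181a-5p ended with DESeq2 size factors, DESeq2 or library size alone. That of miR-5099 ended with loess offsets. Of the 19 higher calls, 10, 12 and 11 stayed without Cre library A, B or C.

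The effect of the AGO2 knockout differed between naive and Th2 cells for 12 of 98 miRNAs, 9 upward and 3 downward. The shift was 5.58 for miR-150-3p (SE 0.57, edgeR adjusted p = 2.6e-07), 4.21 for miR-3962, 1.76 for miR-26b-5p, 2.25 for miR-1198-5p and -2.75 for miR-6236. Those of miR-700-3p (-4.04) and miR-351-5p (-7.60) are fitted values that are no bound, since the 3 naive Cre libraries held 1 count of miR-700-3p and 0 of miR-351-5p. The count was 2 without naive Cre library C, and also without B and C together, where library A alone is assumed to vary like the other groups. It was 5 without Th2 Cre library C, 20 with DESeq2 size factors, 36 with all locus entries, 37 with STD scaling and 3 with a block for the replicate label. The split was 8 and 12 with DESeq2 size factors, 1 and 36 with STD scaling, 7 and 10 with DESeq2, 3 and 9 with no filter, 18 and 18 with all locus entries and 3 and 0 with the block. Differences were 4.59 for miR-150-3p, 3.03 for miR-3962 and -3.35 for miR-6236 without naive Cre C, 1.58 for miR-1198-5p without Th2 Cre A, 4.97 for miR-150-3p, 3.61 for miR-3962 and 1.56 for miR-1198-5p without Th2 Cre C and -3.40 for miR-6236 without Th2 knockout E. Calls of miR-1198-5p and miR-26b-5p ended with no filter. That of miR-1198-5p ended with all locus entries. Those of miR-26b-5p, miR-351-5p, miR-6236 and miR-700-3p ended with a replicate block. Calls of miR-3962 and miR-700-3p (naive Cre C), miR-26b-5p (naive Cre C, Th2 Cre A, B or C), miR-1198-5p (naive Cre C, Th2 Cre A or C), miR-351-5p (naive Cre A or C) and miR-6236 (naive Cre A or C, naive knockout G, Th2 knockout D, F or G) ended without any 1 library in brackets.

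The time in culture was compared in WT cells to give the change in Th2 culture without a knockout. From naive cells to day 7, miR-181a-5p fell to 7073 ± 537 against 40150 ± 4485 CPM (SD, n = 4 and 4; log2 fold change -2.51 with SE 0.16, edgeR adjusted p = 6.1e-14) and miR-150-5p to 20615 ± 1066 against 37795 ± 3976 CPM (log2 fold change -0.87 with SE 0.15, edgeR adjusted p = 6.6e-06), both in all 4 libraries. miR-21a-5p rose to 24046 ± 1757 against 8451 ± 1031 CPM (log2 fold change 1.51 with SE 0.13, edgeR adjusted p = 1.5e-11). The miR-183-96-182 cluster, which cytokine signals induce in T cells, rose in all 4 tested members, with miR-183-5p (3.88), miR-96-5p (2.96) and miR-182-5p (2.05), and edgeR called 4 of 4 tested higher and 0 lower, or 4 adjusted over the list alone (camera adjusted p = 0.000146, or 0.00444 with an estimated correlation). In the miR-181 family edgeR called 0 of 4 tested higher and 4 lower, or 4 adjusted over the list alone (camera adjusted p = 0.000146, or 0.00444 with an estimated correlation), and in the miR-23-27-24 clusters edgeR called 10 of 11 tested higher and 1 lower, or 11 adjusted over the list alone (camera adjusted p = 0.0125, or 0.125 with an estimated correlation), with miR-27a-5p at a count ratio of 34.0 (95% interval 11.4 to 167).

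Among miRNAs induced by T cell activation, from naive cells to day 7, edgeR called 16 of 21 tested higher and 3 lower, or 19 adjusted over the list alone (camera adjusted p = 0.00119, or 0.125 with an estimated correlation). In the Sfmbt2 intron cluster, with 38 distinct sets of counts, edgeR called 1 of 41 tested higher and 34 lower, or 36 adjusted over the list alone (camera adjusted p = 9.7e-07, or 0.0443 with an estimated correlation). Of the core set, 4 of 12 rose, 6 fell and 10 passed adjusted over the list alone. The others besides those named were miR-24-3p (0.97), miR-27a-3p (1.24), miR-17-5p (0.91), miR-146a-5p (-0.53), miR-142a-3p (-0.79), miR-29a-3p (-0.38) and let-7g-5p (-0.32), with miR-155-5p (0.16) and miR-142a-5p (-0.23) not passing. Some miRNAs had 0 counts in naive WT. Against a floor of 3 counts per library, miR-1968-5p was at least 8.39-fold, miR-12188-5p at least 7.74-fold, miR-1941-5p at least 2.03-fold and miR-210-5p at least 1.54-fold higher at day 7. miR-34a-5p, a p53 target, had 177 counts against 2, a ratio of 68.5 (18.7 to 570), and miR-6974-5p had a ratio of 65.7 (11.5 to 2627). miR-6538 (7.05) and miR-210-3p (5.41) also rose. Of the decreases, miR-1247-5p was at least 3.36-fold lower, and count ratios were 100.2 for miR-184-3p (27.3 to 835), or 20.8 (95% interval 5.15 to 182) without naive WT library 1, which held 132 of 155 counts, 27.2 for miR-6899-3p (7.06 to 232) and 16.8 for miR-7072-5p (5.34 to 85.0). miR-181a-2-3p (-9.21), miR-211-5p (-8.63), miR-200b-5p (-4.36) and miR-181a-1-3p (-3.88) also fell. Log2 values were -9.72 for miR-211-5p (on 2 counts) without day 7 WT 1 and -10.19 for miR-181a-2-3p (on 2 counts) without day 7 WT 2.

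Of 382 miRNAs tested between naive and day 7 WT cells, edgeR called 292, with 151 higher and 141 lower. The split was 200 and 70 with STD scaling, under which the values of miR-146a-5p, miR-29a-3p and let-7g-5p turned positive. The call of let-7g-5p ended with DESeq2 size factors, DESeq2 or loess offsets. Those of let-7g-5p and miR-29a-3p ended with library size alone, no filter or all locus entries. Calls of let-7g-5p (naive WT 2, 3 or 4, day 7 WT 2, 3 or 4) and miR-29a-3p (naive WT 4) ended without any 1 library in brackets.

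Between day 7 and day 14 in WT cells, miR-10a-5p rose to 1559 ± 44.0 against 147 ± 15.4 CPM (log2 fold change 3.41 with SE 0.29, edgeR adjusted p = 1.2e-10; SD, n = 3 and 4) and miR-155-5p to 16691 ± 870 against 9598 ± 413 CPM (log2 fold change 0.80 with SE 0.13, edgeR adjusted p = 1.0e-05). miR-150-5p fell to 10393 ± 1982 against 20615 ± 1066 CPM (log2 fold change -0.99 with SE 0.17, edgeR adjusted p = 1.4e-05) and miR-181a-5p to 2248 ± 402 against 7073 ± 537 CPM (log2 fold change -1.65 with SE 0.18, edgeR adjusted p = 1.5e-08). All 3 day 14 libraries lay beyond every day 7 library for these 4 miRNAs. In the miR-183-96-182 cluster edgeR called 4 of 4 tested higher and 0 lower, or 4 adjusted over the list alone (camera adjusted p = 0.000708, or 0.0138 with an estimated correlation), and in the miR-181 family edgeR called 0 of 4 tested higher and 4 lower, or 4 adjusted over the list alone (camera adjusted p = 0.000105, or 0.00423 with an estimated correlation). Markers of epithelial, liver and muscle cells moved too: edgeR called 0 of 8 tested higher and 6 lower, or 8 adjusted over the list alone (camera adjusted p = 0.00221, or 0.0523 with an estimated correlation), among them miR-122-5p (-4.24), miR-141-3p (-1.23), miR-200a-3p (-1.15) and miR-429-3p (-0.97).

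The other large rises from day 7 to day 14 were miR-152-3p (4.05), miR-12184-5p (3.95), miR-672-5p (3.92), miR-147-3p (3.88), miR-1948-3p (3.58), miR-23b-5p (3.57) and miR-10b-5p (3.15), and the decreases were miR-143-3p (-3.57), miR-139-5p (-3.21), miR-181b-5p (-2.32), miR-15a-3p (-2.29), miR-874-3p (-2.17), miR-139-3p (-2.16) and miR-15b-3p (-2.07). Log2 values were 4.55 for miR-147-3p without day 7 WT 3, 5.24 for miR-672-5p (on 2 counts) without day 7 WT 4 and 2.95 for miR-672-5p and -4.48 for miR-143-3p (on 3 counts) without day 14 WT 3. Of the core set, 3 of 12 rose, 2 fell and 5 passed adjusted over the list alone, with miR-24-3p (0.36) and miR-27a-3p (0.38) among the rises and miR-146a-5p (0.07), miR-21a-5p (0.24), miR-142a-3p (0.06), miR-142a-5p (-0.16), miR-17-5p (-0.50), miR-29a-3p (-0.26) and let-7g-5p (-0.16) not passing. Of 382 miRNAs tested, edgeR called 191, with 96 higher and 95 lower. The split was 75 and 113 with library size alone and 52 and 89 with STD scaling. The call of miR-24-3p (day 7 WT 2, 3 or 4, day 14 WT 2) ended without any 1 library in brackets. Calls of miR-24-3p and miR-27a-3p ended with library size alone or no filter. That of miR-24-3p ended with loess offsets.

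In Cre cells, naive and Th2 cells were compared at lower depth. miR-146a-5p rose to 6778 ± 1823 against 369 ± 640 CPM (log2 fold change 3.32 with SE 0.73, edgeR adjusted p = 0.000727; SD, n = 3 and 3), where all 8 naive counts lay in library A and the value ran down to 2.56 under the alternatives and up to 10.46, a fit against 0 counts that is no bound. miR-150-3p and miR-150-5p fell to 319 ± 30.0 against 12010 ± 8165 CPM and 651 ± 57.1 against 8368 ± 4705 CPM (log2 fold changes -5.24 and -3.81, edgeR adjusted p = 3.3e-08 and 3.9e-06). All 3 Th2 libraries lay beyond every naive library for these 3. Among miRNAs induced by T cell activation edgeR called 8 of 8 tested higher and 0 lower, or 8 adjusted over the list alone (camera adjusted p = 0.00283, or 0.232 with an estimated correlation), with miR-155-5p (1.63), miR-210-3p (4.15) and miR-183-5p (4.01). Among those lost on activation edgeR called 1 of 10 tested higher and 5 lower, or 6 adjusted over the list alone (camera adjusted p = 0.0275, or 0.232 with an estimated correlation), and the median of -1.16 became 1.55 with STD scaling. The 1 member called higher was miR-146a-5p, which is also in the list induced by activation. The Sfmbt2 intron cluster, again with 2 distinct measurements, was not read as a list. Library A also held 6 of 7 naive counts of miR-148a-3p and 7 of 8 of miR-210-3p. miR-6240 (4.31) and miR-148a-3p (4.27) rose and miR-3962 (-3.33), miR-30a-3p (-3.34), miR-30e-5p (-3.08), miR-26b-5p (-2.57) and miR-181a-5p (-2.39) fell. Log2 values were 5.41 for miR-148a-3p (on 1 count), -4.53 for miR-30a-3p, -4.03 for miR-3962, -2.28 for miR-30e-5p (on 3 counts), -1.63 for miR-181a-5p, 2.004 for miR-27a-3p (on 2 counts), 5.46 for miR-210-3p (on 1 count) and 4.65 for miR-183-5p without naive Cre A, -4.64 for miR-150-3p, -1.66 for miR-30a-3p (on 2 counts), -2.56 for miR-3962, 2.72 for miR-146a-5p and 3.27 for miR-183-5p without naive Cre C and -2.68 for miR-30a-3p without Th2 Cre A. miR-6538 had 888 counts against 1, a ratio of 50.9 (9.11 to 2012), miR-212-5p had 520 against 1, a ratio of 29.8 (5.33 to 1179), and miR-181a-2-3p had 2 against 16, a ratio of 140 lower (32.8 to 1251). miR-351-5p, miR-21a-3p, miR-130b-5p and miR-322-3p were listed at 0 in naive Cre, and no fold is given because the Th2 level lay below the highest floor of the naive libraries.

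Of 98 miRNAs tested in Cre cells, edgeR called 55, with 36 higher and 19 lower. The core set had 5 of 11 tested members higher, 3 lower and 8 adjusted over the list alone, with miR-21a-5p (1.098), miR-24-3p (1.62), miR-27a-3p (1.33) and miR-142a-5p (-1.21) among the calls and miR-142a-3p (-0.39) and let-7g-5p (-0.24) not passing; miR-29a-3p had 3 counts in naive Cre, a ratio of 1.87 (0.622 to 9.23). The count was 84 with STD scaling, which split 82 and 2, and loess offsets split 21 and 25. The calls of miR-155-5p, miR-21a-5p, miR-24-3p, miR-27a-3p, miR-30a-3p and miR-322-3p ended without naive Cre libraries B and C together, where library A alone is assumed to vary like the other groups. All of these but that of miR-155-5p also ended without C alone. Those of miR-30e-5p, miR-181a-5p, miR-130b-5p, miR-322-3p, miR-21a-5p and miR-24-3p ended without library A. The call of miR-142a-5p ended when any 1 of the 6 libraries was left out. The call of miR-142a-5p ended with no filter or all locus entries. Those of miR-130b-5p, miR-155-5p, miR-21a-5p, miR-24-3p, miR-27a-3p and miR-322-3p ended with loess offsets. Those of miR-142a-5p and miR-21a-5p ended with a replicate block.

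The effects of the 2 knockouts were compared with each other, which the labels put in different experiments with different controls and, for Th2 cells, different days, so that knockout and experiment cannot be separated. In naive cells, the effects differed for 8 of 376 miRNAs, 5 upward and 3 downward (AGO2 effect minus AGO134 effect), with miR-3963 (2.95), miR-181a-2-3p (2.76), miR-181a-1-3p (3.41) and miR-182-5p (2.23) upward, where the value of miR-181a-1-3p is fitted on 2 counts in naive Cre, and miR-669a-5p (-1.71), miR-669p-5p (-1.71) and miR-3962 (-2.85) downward. In Th2 cells, at day 5 for AGO2 and day 7 for AGO134, they differed for 87 of 376, 38 upward and 49 downward, led by miR-150-3p (4.94), miR-25-5p (4.24), miR-92a-1-5p (3.23) and miR-150-5p (3.09) and by miR-212-5p (-2.31), miR-212-3p (-3.27), miR-298-5p (-3.40) and miR-99b-5p (-2.14). The difference was -4.13 for miR-298-5p (on 3 counts) without Th2 AGO2 knockout G. Over 376 miRNAs, not independent replicates, Pearson correlation of the 2 effects was -0.026 in naive (Spearman 0.005) and 0.098 in Th2 cells (Spearman 0.083). Only 98 passed the filter in the AGO2 experiment, so values near 0 do not show unrelated effects. The naive count was 14 with DESeq2 size factors, library size alone or loess offsets, 16 with DESeq2, 13 with no filter, 44 with all locus entries, 5 with STD scaling, 20 without naive Cre library A and 16 without naive AGO2 knockout library F. The splits were 5 and 9 with DESeq2 size factors, 2 and 12 with library size, 4 and 1 with STD scaling, 4 and 10 with loess, 6 and 10 with DESeq2 in naive cells, and 9 and 108 with STD scaling in Th2 cells. Differences were 2.81 for miR-182-5p and -3.54 for miR-3962 without naive Cre A and -2.03 for miR-3962 without naive Cre C. Calls of miR-181a-1-3p and miR-182-5p ended with library size alone. That of miR-182-5p ended with loess offsets. The call of miR-181a-1-3p ended without naive Cre library A and that of miR-3962 without C, and both and that of miR-182-5p ended without B and C together, where library A alone is assumed to vary like the other groups.

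The minor arm of a hairpin is the less abundant of its 2 mature miRNAs. Its share did not pass the two-sided exact permutation test in any comparison. Over 94 hairpins, the library median of the log2 ratio of minor to major arm differed between AGO134 knockout and WT by -0.04 in naive cells (-2.81 ± 0.178 and -2.77 ± 0.128, SD, n = 4 and 4; exact p = 0.771), by -0.06 at day 7 (-2.45 ± 0.0494 and -2.39 ± 0.102, exact p = 0.486) and by -0.23 at day 14 (-2.64 ± 0.169 and -2.41 ± 0.244, n = 3 and 3, exact p = 0.3). Over 9 hairpins it differed between AGO2 knockout and Cre by -0.28 in naive cells (exact p = 0.229) and by 0.38 in Th2 cells (exact p = 0.457). In Th2 cells 3 of 4 knockout libraries lay above every Cre library and library E (-2.68) below all; the difference was 0.73 without E (exact p = 0.1, the smallest for 3 against 3), 0.58 with a pseudocount of 5 (exact p = 0.0571) and 1.09 with libraries thinned to 1 depth (exact p = 0.171). In naive cells it was -0.83 with a pseudocount of 5 (exact p = 0.114). The smallest p allowed is 0.0286 for 4 against 4, 0.1 for 3 against 3 and 0.0571 for 4 against 3. With no filter on hairpins the AGO134 differences turned positive (0.43, 0.12 and 0.33 at naive, day 7 and day 14).

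The ratio of miRNA counts to counts of the STD entries was lower in the AGO134 knockout at each stage and in Th2 cells of the AGO2 knockout. In naive cells it was 1.03 ± 0.0787 in WT and 0.733 ± 0.134 in the AGO134 knockout (SD, n = 4 and 4), 29.5% lower as a geometric mean, and all 4 knockout libraries lay below every WT library (two-sided exact permutation p = 0.0286, the smallest the design allows). At day 7 it was 1.39 and 1.12, 19.98% lower, again in all 4 libraries (exact permutation p = 0.0286). At day 14 it was 1.35 and 1.095, 18.8% lower in all 3 libraries (exact permutation p = 0.1, the smallest the design allows). In Th2 cells of the AGO2 experiment it was 1.48 in Cre and 0.539 in the knockout, 63.8% lower in all 4 libraries (exact permutation p = 0.0571, the smallest the design allows), while in naive cells it was 1.63-fold higher in the knockout (exact permutation p = 0.286), or 17.4% lower without STD.A (exact permutation p = 0.514), neither of which passed. Scaling to the STD entries shifted the median log2 fold change of all miRNAs to -0.77 in naive cells, -0.63 at day 7 and -0.44 at day 14 of the AGO134 comparison, to -1.59 in AGO2 Th2 cells, to 0.73 between naive and day 7, -0.22 between day 7 and day 14 and 3.30 in Cre cells. Library size alone shifted it to -0.34, -0.31 and -0.15 in the 3 AGO134 comparisons, to -0.32 and -0.19 in naive and Th2 cells of the AGO2 experiment, and to 0.29, -0.17 and 0.86 in the 3 comparisons of time. DESeq2 size factors shifted it to 0.20 between naive and day 7, to 0.31 and -0.11 in naive and Th2 cells of the AGO2 experiment, and to 0.67 in Cre cells.

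**Figure D3:**
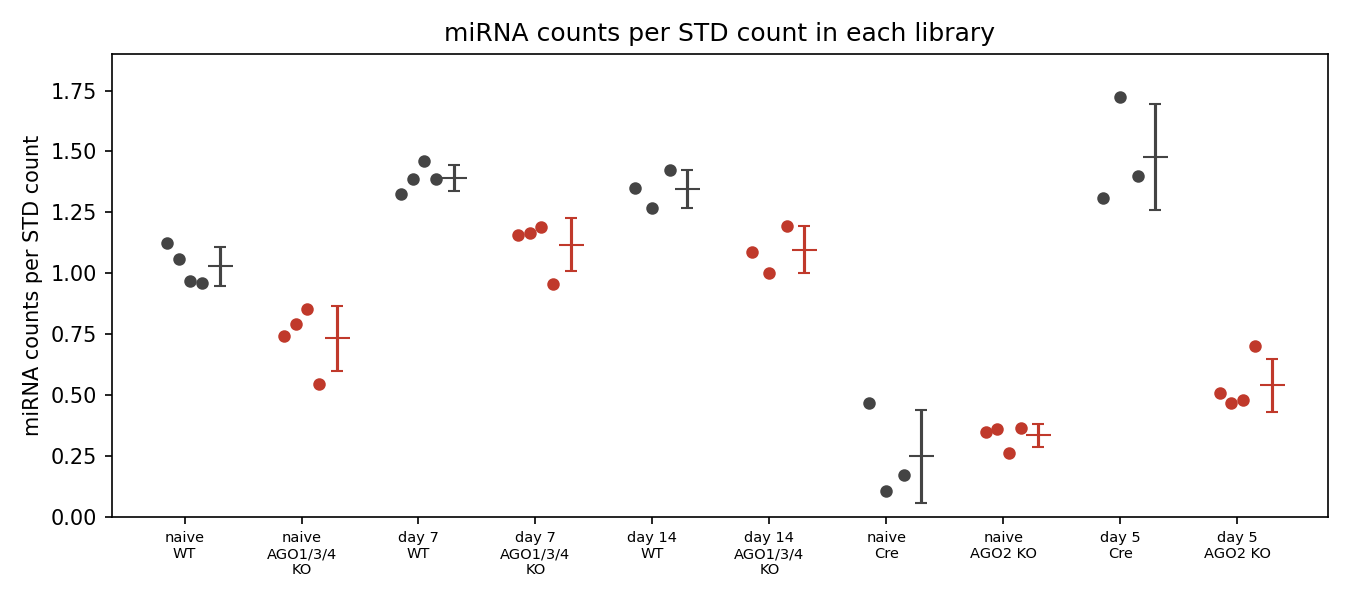
miRNA counts per count of the STD entries (linear axis) for each library of the 10 groups, with controls in grey and knockouts in red, with a point per library and a dash and bar for the mean ± SD. The naive AGO134 knockout averaged 0.733 against 1.03 in WT.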

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

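The splits of the libraries, the tests of a difference between stages and the fits without 1 library were planned; the tests of STD.A, input, activation, leftover naive cells, the library rich in miR-5099, depth and abundance were chosen after the result was seen. A library was singled out when its gap to the nearest other library of a group of 4 was most of the range of the group (Dixon's test), which chance gives in about 1 in 20 groups; 17 of 176 groups met it where 8.8 would be expected.

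Knockout library 4 at day 7 of the AGO134 experiment stood apart in miRNA counts (125803), miRNAs detected (530), miRNA per STD count (0.954) and STD share (45.4%). The naive AGO2 knockout library F stood apart in STD share (76.3%), and day 7 WT library 3 in the minor arm ratio (-2.24). The Th2 AGO2 knockout library E stood apart in miR-155-5p (24145 CPM), miR-142a-3p (23195), miR-142a-5p (7460) and miR-5099 (795145). The naive AGO134 knockout library 4 stood apart in miR-142a-5p (5729 CPM), let-7a-5p (108400) and miR-92a-3p (8594). Single miRNAs also stood apart in the naive AGO2 knockout library G (miR-27a-3p, 510.2 CPM) and E (miR-150-3p, 4078), in naive WT library 1 (miR-10a-5p, 1020) and in day 7 WT library 2 (miR-222-3p, 389.9).

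The effect of a knockout differed between stages by the test of the difference itself. From naive cells to day 7 in the AGO134 experiment the named miRNAs, of 9 called, were miR-182-5p (0.93), miR-351-5p (0.94), miR-1839-3p (1.68), miR-542-5p (1.05), miR-15b-3p (-1.22) and miR-181a-5p (-0.86). From day 7 to day 14 those named, of 46, were miR-181b-5p (1.29), miR-222-3p (1.52), miR-221-3p (1.38), miR-15b-3p (1.38), miR-212-5p (-2.76), miR-212-3p (-2.32), miR-132-5p (-1.95) and miR-146b-5p (-1.62). In the AGO2 experiment those named, of 12, were miR-150-3p (5.58), miR-3962 (4.21), miR-26b-5p (1.76), miR-1198-5p (2.25), miR-700-3p (-4.04), miR-351-5p (-7.60) and miR-6236 (-2.75), where the values of miR-351-5p and miR-700-3p are fitted values against naive Cre libraries with 0 counts and 1 count.

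Calls were set against other splits of the libraries. For AGO134 in naive cells, no other split gave as many (70 calls, highest other 6, 1 of 35 splits). This held at day 7 (55, highest other 1, 1 of 35). Splits were too few at day 14 (75, highest other 0, 1 of 10). For AGO2 the same held in Th2 cells (44, highest other 20, 1 of 35), not naive cells (9, highest other 10, 2 of 35). In WT cells it held from naive to day 7 (292, highest other 0, 1 of 35). It also held from day 7 to 14 (191, highest other 118, 1 of 35). Splits were too few for Cre cells (55, highest other 0, 1 of 10). At 1 of 35, the lowest possible, chance and effects of depth stay open. Splits for differences of effects redrew genotype labels, so they cannot test these alone. AGO134 gave 9 calls from naive cells to day 7 (highest other 30, 3 of 100). It gave 46 from day 7 to 14 (highest other 55, 2 of 100). AGO2 gave 12 between stages (highest other 5, 1 of 100). Between knockouts it was 87 in Th2 cells (highest other 78, 1 of 100) and 8 in naive cells (highest other 12, 7 of 100). The high counts from naive cells to day 7 and from day 7 to day 14 of the AGO134 effect and between the knockouts in Th2 cells came from splits that kept 1 stage or experiment as it was and nearly exchanged the labels of the other. Those of naive and Th2 AGO2 cells and of day 7 to day 14 in WT cells came from near-mirrors of the real split, in which 1 of 7 libraries kept its label; for naive AGO2 cells this was the only other split as large. That between the knockouts in naive cells nearly exchanged the labels of both experiments.

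The ratio of miRNA counts to STD counts was a signal in entries that the other comparisons do not use, lower in the knockout by 29.5% in naive cells, 19.98% at day 7 and 18.8% at day 14 of the AGO134 experiment, and by 63.8% in Th2 cells of the AGO2 experiment. A different share of the entry STD.A was argued against for the AGO134 experiment, since without it 11 of 11 knockout libraries still lay below every control of their stage. A different input of RNA or of standard per library stays open, since the ratio varied by 1.57-fold between the highest and lowest naive AGO134 knockout libraries and the labels give no input. A lower content of miRNA per cell in the knockout, the biological explanation the design gives, stays open and untested.

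Of the 19 miRNAs called higher in Th2 cells of the AGO2 knockout, 10, 12 and 11 were still called without Cre library A, B or C and 16, 18, 15 and 15 without knockout library D, E, F or G, where the counts of miR-25-5p, miR-92a-1-5p and miR-3535 were too low for the test without D, F or G. That library E, rich in miR-5099, caused them was argued against by the 18, among 50 calls in both directions, and miR-5099 itself was not called. Naive knockout cells left in the culture were argued against for 10 of the 19 (miR-25-5p, miR-92a-1-5p, miR-23a-5p, miR-30b-3p, miR-1198-5p, miR-125a-5p, miR-296-3p, miR-30e-3p, miR-3535 and miR-21a-3p), which were called above both the Th2 Cre cells and naive knockout cells, though miR-1198-5p at 1775 CPM was not above naive Cre cells (1858) and the call above Th2 Cre cells ended for miR-21a-3p and miR-3535 without Cre library A, B or C, for miR-30e-3p without A or C and for miR-296-3p without A, and stay open for the others, of which 88.9% lay between the Th2 Cre level and the higher of both naive levels; an earlier form of the test, in which 9 of 19 lay between, was replaced after being seen. Cells less far along activation stay open, since the AGO2 effect had a Spearman rho of -0.446 across 98 miRNAs with the WT change from naive to day 7, while other splits reached -0.503 and 4 of 35 were as low. A direct effect of the loss of AGO2, the biological explanation the design gives, was not tested.

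Higher AGO134 calls tended to be abundant and lower ones scarce miRNAs. Abundance as the whole cause was argued against in naive cells and at day 14. With loess offsets 44 of 70 and 60 of 75 calls kept direction there (62.9% and 80%). This cause stays open at day 7, outside the test, where 27 of 55 did (49.1%). Compression of counts in shallow libraries stays open, since the slope on abundance and the depth within groups had r = -0.259 over 22 libraries (permutation p = 0.204; Spearman -0.451, permutation p = 0.0359) and r = -0.792 without the 2 libraries farthest in depth, naive knockout libraries 3 and 4 (permutation p = 0.00045; Spearman -0.675, permutation p = 0.00115), so that the relation rests on which libraries are used. An effect of the knockout on abundant miRNAs, the biological explanation the design gives, was not tested.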

How the results depend on the processing

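The alternatives that used all locus entries, scaling to the STD entries, loess offsets, depth thinning of the arm test and the joint removal of naive Cre libraries B and C were chosen after seeing the data; the others were planned. Outside scaling to the STD entries, 289 named results took 4603 values, of which 4124 kept their side of the threshold, 413 lost the call and 66 gained one; 0 values with a call changed sign, while values without one could. For 203 results, some never called, no value lost a call. The shallowest library, naive Cre B with 596 counts, enters every comparison with naive Cre cells. For the moved results below the cause was not tested, except that no filter, all locus entries and a fit of fewer groups change the miRNAs or libraries tested.

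With DESeq2 size factors the count was 20 for the AGO2 effect between stages and 14 between the knockouts in naive cells. With library size alone it was 3 for the AGO134 effect from naive to day 7, 14 for naive AGO2 and 14 between the knockouts in naive cells. With no filter it was 35 for AGO134 at day 7, 76 for AGO2 Th2 and 13 between the knockouts in naive cells. With all locus entries it was 31 for naive AGO2, 71 for AGO2 Th2, 36 for the AGO2 effect between stages and 44 between the knockouts in naive cells. With loess offsets it was 14 and with DESeq2 16 between the knockouts in naive cells, and with DESeq2 14 for the AGO134 effect from naive to day 7. With the Th2 groups fitted alone it was 79 for AGO2 Th2. With a block for replicate labels, whose residual correlations of -0.306 to 0.1501 gave no sign that the labels pair samples, it was 5 for the AGO134 effect from naive to day 7 and 3 for the AGO2 effect between stages. Without naive Cre libraries B and C, which leaves library A alone, assumed to vary like the other groups, it was 0 for naive AGO2 (edgeR, 21 at an unadjusted p under 0.05, and 3 by DESeq2) and 2 for the AGO2 effect between stages. With scaling to the STD entries it was 204 for AGO134 naive, 129 at day 7, 1 and 15 for the AGO134 effect from naive to day 7 and from day 7 to day 14, 5 for naive AGO2, 69 for AGO2 Th2, 84 for Cre cells, 37 for the AGO2 effect between stages and 5 between the knockouts in naive cells. With an estimated correlation 7 of 20 lists passed, namely 0 for AGO134 naive (4 at an unadjusted p under 0.05), 2 at day 7, 0 for naive AGO2 (1 at an unadjusted p under 0.05), 3 from naive to day 7, 2 from day 7 to day 14 and 0 for Cre cells (0 at an unadjusted p under 0.05); the Sfmbt2 list, counted among the 20 for naive AGO2 and Cre cells, holds 2 distinct measurements there and is not read. The correlation of effects in Th2 cells was 0.0301 over miRNAs of at least 100 CPM.

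Leaving out 1 library at a time, the count ran from 37 to 73 for AGO134 naive, 24 to 59 at day 7, 55 to 67 at day 14, 4 to 18 for naive AGO2, 32 to 50 for AGO2 Th2, 277 to 292 from naive to day 7, 165 to 189 from day 7 to day 14, 42 to 58 for Cre cells, 3 to 15 and 30 to 51 for the AGO134 effect from naive to day 7 and from day 7 to day 14, 2 to 18 for the AGO2 effect between stages, and 7 to 20 and 72 to 89 between the knockouts in naive and Th2 cells. The minor arm difference ran from -0.12 to 0.02, -0.08 to -0.01 and -0.37 to -0.14 in naive, day 7 and day 14 AGO134 cells and from -0.41 to -0.16 and 0.20 to 0.73 in naive and Th2 AGO2 cells.

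Scaling to the STD entries gave 40 reversed values. For AGO134 in naive cells these were let-7a-5p -0.0990, let-7c-5p -0.18, miR-150-5p -0.16, let-7f-5p -0.21, miR-3963 -0.15, miR-155-5p -0.35, miR-146a-5p -0.26, miR-21a-5p -0.55, miR-181a-5p -0.26, miR-24-3p -0.63, miR-27a-3p -0.59, miR-29a-3p -0.57 and let-7g-5p -0.23. At day 7 they were miR-155-5p -0.12, miR-146a-5p -0.17, miR-24-3p -0.25, let-7g-5p -0.19, let-7i-5p -0.0695, miR-25-3p -0.14, miR-93-5p -0.17, miR-17-3p -0.19, miR-23a-3p -0.0886, miR-27b-3p -0.13, miR-30e-5p -0.0402 and miR-182-5p -0.0462. From naive to day 7 they were miR-146a-5p 0.11, miR-29a-3p 0.24 and let-7g-5p 0.30. For AGO2 in Th2 cells they were miR-5099 -0.37, miR-142a-3p -1.23, miR-181a-5p -0.41 and miR-27a-3p -1.46. In Cre cells they were miR-26b-5p 0.20, miR-181a-5p 0.25, miR-142a-3p 2.05, miR-142a-5p 1.51, let-7g-5p 2.53, miR-669a-5p 0.91, miR-669p-5p 0.91 and miR-669c-5p 1.495.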

Other observations

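The values below were chosen after they were seen, and no hypothesis was tested on them. The miR-132/212 hairpins lie next to each other on chromosome 11, at 75173682 to 75173747 and 75173388 to 75173478. miR-212-5p stood at 376 ± 118 against 575 ± 56.6 CPM in AGO134 knockout and WT naive cells (edgeR adjusted p = 0.0846), at 1486 ± 354 against 1196 ± 147 CPM at day 7 (adjusted p = 0.329) and at 467 ± 143 against 2553 ± 139 CPM at day 14 (adjusted p = 3.5e-09; SD, n = 4 and 4, 4 and 4, 3 and 3). miR-132-3p and miR-212-3p had log2 fold changes of -1.75 and -1.81 at day 14. miR-132-5p had 0.67 at day 7 and -1.28 at day 14.

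Several miRNAs lower in the knockout at day 14 were higher in WT cells at day 14 than at day 7. Both comparisons use the same 3 day 14 WT libraries with opposite sign, so chance in these libraries would give this pattern too. miR-10a-5p rose by 3.41 in WT (adjusted p = 1.2e-10) and was -2.28 in the knockout relative to WT, and miR-152-3p, in an intron of Copz2 at 96850393 to 96850465 of the same chromosome, rose by 4.05 and was -2.10. miR-146b-5p rose by 1.49 (adjusted p = 2.2e-08) and miR-212-5p by 1.09 (adjusted p = 2.0e-05). The neighbours miR-221-3p and miR-222-3p on chromosome X were at 1.06 and 1.58 in the knockout at day 14.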
